A study of Mus musculus with 8 samples.

How the data were processed

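Single-cell mRNA counts were read from 6 droplet libraries of tumour-bearing mouse liver, 3 control and 3 labelled knockout. The deposited matrices hold raw counts of UMIs per gene and cell barcode, made by the authors with Cell Ranger 7.0.1 for the libraries numbered 1 and 2 and 9.0.1 for those numbered 3, per the file headers, while the submitters' processing notes name 9.0.1 and the genome GRCm39. Per the labels' protocols, tissue was dissociated with enzymes and libraries were made with 10x 3′ chemistry. All 6 files list the same 33696 genes. The matrices of replicates 1 and 2 hold only barcodes already called as cells (3632, 4592, 1442 and 1021 in control 1, knockout 1, control 2 and knockout 2), and those of replicate 3 hold all barcodes (2207809 and 1715660 in control 3 and knockout 3). The 2 hashtag libraries have no files of their own, and their counts, 86409082 and 73241922 UMIs over 3 features, sit in the matrices of replicate 3, where they stayed out of library sizes and tests. No 2 libraries were copies of each other.

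Barcodes were kept with at least 500 UMIs, 300 genes and at most 20% mitochondrial counts. In replicate 3, barcodes also had to differ from the profile of barcodes with at most 100 UMIs (10000 multinomial simulations, false discovery rate 0.001), which removed 184 and 131. The automatic threshold of Scrublet (in scanpy) called 1 to 4 doublets per library, too few for the loading, so after this was seen the cells with the highest scores were removed at 0.8% per 1000 cells: 58, 62, 2, 0, 791 and 205 in control 1, knockout 1, control 2, knockout 2, control 3 and knockout 3. In replicate 3, hashtags marked 571 and 144 barcodes as multiplets, of which Scrublet had called 23.3% and 9.7%, against 6.9% and 4.9% of single barcodes, so doublets remain. Hashtags gave 3301, 3644 and 1535 cells to the 3 mice of control 3 and 1565 and 1854 to the 2 mice of knockout 3, and left 893 and 1503 unassigned. The 20049 kept cells held 37932212, 2175184 and 81102232 UMIs in controls 1, 2 and 3 and 28717420, 887170 and 60995180 in knockouts 1, 2 and 3. Their NK-like cells held 1716778, 577600 and 4322420 UMIs and 1081648, 148766 and 982818 UMIs, so that a gene with no UMI in knockout 2 may still lie at up to 20.2 CPM in its NK-like cells.

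Counts were scaled to 10000 per cell, 2000 variable genes were reduced to 30 principal components without batch correction, and a graph of 15 neighbours was clustered with Leiden at resolution 1. A cluster was named after 1 of 19 classes when at least 3 of the markers fixed for that class were 2-fold higher than in all other cells and detected in 10% of its cells. A cluster was called mixed when the runner-up class reached 0.7 of the marker share of the best class, a threshold moved from 0.8, which was tried first, and both were set after the clusters were seen. Named classes numbered 16, and 2.387%, 3.473% and 0.896% of cells in controls 1, 2 and 3 and 0.663%, 2.239% and 0.905% in knockouts 1, 2 and 3 stayed unnamed. NK-like cells, 1416 in all, were clustered again at resolution 0.5 on 20 components.

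UMIs were summed per library and class where a library held at least 10 cells, and classes with 3 such libraries per group were compared, libraries labelled knockout against control, with the edgeR quasi-likelihood test (TMM scaling, filterByExpr, two-sided, Benjamini-Hochberg adjustment within the class, threshold 0.05). The standard error was the absolute log2 fold change divided by the square root of the F statistic. Of 38 gene lists written for this comparison, 22 were tested in NK-like cells and those of a class, or of all classes, in the 5 other classes (82 tests), where at least 3 members were measured, with camera of limma at a preset correlation of 0.01, adjusted over all lists of NK-like cells or over all lists and classes together. Camera ranks a list against the other genes, so its direction can differ from the sign of the median. Shares of classes were tested with edgeR on cell numbers and with exact two-sided permutation tests of 3 against 3 libraries, whose smallest p is 0.1, or of 3 pairs, whose smallest p is 0.25. Libraries, not cells, were the units, except in an alternative with mice as units. There the libraries numbered 3 were split into mice, keeping only cells that hashtags gave to 1 mouse, and the other libraries stayed whole. The mice of knockout 3 then held 90 and 53 of its 179 NK-like cells. The tests, the markers, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

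Named genes in NK-like cells were Nr4a1, Nr4a2 and Nr4a3, up to 10 genes per direction that passed, the 10 smallest p where fewer than 10 passed, and the 2 members of each list with the smallest p. In other classes they were Nr4a1, up to 4 genes per direction that passed and the 2 members of each passing list with the smallest p. This gave 122 named genes, 49 of them in NK-like cells. A few genes that meet it are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

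Whether libraries of the same number belong together was checked by the correlation of their deviations from the group means. In NK-like cells these were 0.352, 0.334 and 0.29 for numbers 1, 2 and 3, each library correlating best with its own number, and in the other classes they ran from 0.11 to 0.664, with the exception of number 3 in neutrophils (0.053). The numbers were therefore taken to pair the libraries, for which the labels give no reason, and values with the number as a block stand beside the results they change. In neutrophils the pairing is not borne out for number 3. In endothelial cells control 2 correlated better with number 1 than with its own number, at 0.11.

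The alternatives were the block, mice split by hashtag as units with the block, median-of-ratios scaling, DESeq2, no filter on low counts, stricter cells (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, Leiden resolution 2, barcodes of replicate 3 kept by 1000 UMIs alone, NK-like cells taken cell by cell, background genes left out, an estimated correlation, and each library left out in turn. On counts simulated with the measured spread, the test recovered 50% of genes changed 2-fold and 100% of those changed 4-fold in NK-like cells, with 7 wrong calls among 8063 genes. In simulation it recovered 29% and 97% in T cells (3 wrong calls, 10099 genes) and 12% and 84% in monocytes (3 wrong calls, 8596 genes). Of 40 lists of unchanged genes, 0 were called in each class and the changed list was found. Genes were drawn independently, so lists whose members move together were not tested. In NK-like cells the estimated correlation reached 0.828, for the hepatocyte genes. A 16-fold change of a class share was found in 44 of 50 simulations, with 3 wrong calls. The ambient test called 0 of 300 simulated empty barcodes and 89.3% and 94.3% of 300 thinned cells in control 3 and knockout 3. Classes with fewer than 3 libraries per group appear only among the other observations. No coordinates are given, since the reference at hand was of another genome build.

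Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, statsmodels 0.14.6, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.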

Results

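Droplet single-cell RNA-seq was read from livers of mice with hepatocellular carcinoma, raised by pushing plasmid DNA into the tail vein so that it enters hepatocytes. The plasmids disrupt the tumour suppressor gene Trp53 and insert the oncogene c-Myc. Control mice were floxed for Nr4a1 and lacked Cre. In the mice labelled knockout, Cre is expressed from Ncr1, the gene of the activating receptor NKp46, so that the floxed part of Nr4a1 is removed in Ncr1-expressing cells, chiefly natural killer (NK) cells and group 1 innate lymphoid cells (ILC1). Nr4a1 encodes Nur77, a nuclear receptor induced by receptor signalling in lymphocytes. The comparison asks how NK-like cells, and the cells around them in the tumour-bearing liver, differ between the groups. Each group had 3 mRNA libraries. Controls 1 and 2 and knockouts 1 and 2 are called biological replicates in the labels, which do not say which animals lie behind each, and control 3 pooled 3 mice and knockout 3 pooled 2 mice. The deposited matrices held 44326754, 4126740 and 122609032 gene UMIs in controls 1, 2 and 3, and 34369055, 4232577 and 88186316 in knockouts 1, 2 and 3. After filtering, 2639, 547 and 9153 control cells and 2715, 134 and 4861 cells of the libraries labelled knockout were kept, with median depths of 2899, 2156 and 3417 and of 3868, 1924.5 and 2618 UMIs. Knockout 2 was the poorest library, since the median mitochondrial share of its barcodes with at least 500 UMIs was 75.1%, against 27.9% in control 2 and 6.7% to 10.0% in the other libraries.

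Nr4a1 itself (ENSMUSG00000023034) was read at 87.07, 32.16 and 58.41 CPM (UMI counts scaled to the library total) in the NK-like cells of controls 1, 2 and 3, and at 138.60, 0 and 73.62 CPM in knockouts 1, 2 and 3. The group means were 59.2 ± 27.5 and 70.7 ± 69.3 CPM (SD, n = 3 libraries each), and the log2 fold change of the libraries labelled knockout against control was 0.49 with a standard error (SE) of 0.51 (adjusted p = 1, edgeR quasi-likelihood test). The 0 in knockout 2 stands for none of 148766 UMIs in 37 cells, which allows up to 20.2 CPM of that plain total for counting error alone. Without knockout 1 the sign turned, to -0.22. UMIs of Nr4a1 were thus present in NK-like cells of 2 of the 3 libraries labelled knockout. These reads come from the 3′ end of transcripts and the labels do not say which part of the gene is floxed, so the counts check neither the deletion nor the labels, and the label knockout is used below as the depositors gave it. The 2 related receptors gave log2 fold changes of 0.30 (SE 0.41) for Nr4a2 and 0.41 (SE 0.31) for Nr4a3, neither of which passed.

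The share of NK-like cells with an Nr4a1 UMI was 17.97%, 8.70% and 18.14% in controls 1, 2 and 3 and 26.36%, 0% and 17.32% in knockouts 1, 2 and 3, at median depths of 3803.5, 2442 and 4959 and of 6938, 1985 and 3906 UMIs. The 0 of 37 cells in knockout 2 has an exact binomial upper limit of 9.49%. Thinned to 1000 UMIs per cell, with 14, 28 and 19 control cells and 1, 6 and 8 cells of the libraries labelled knockout left out, the shares were 6.85%, 6.77% and 4.30% and 10.09%, 0% and 4.68%. In hepatocytes, a comparison class whose Ncr1 counts were too low to test, the shares were 7.55%, 0% and 11.55% and 7.35%, 0% and 8.04% at median depths of 51302, 3510.5 and 5075 and of 73812, 3834 and 8613 UMIs, and thinned they were 0%, 0% and 0.24% and 0%, 0% and 0.49%. In the other classes tested in all 6 libraries, the Nr4a1 log2 fold change was 0.50 (SE 0.27) in T cells, with 63.7 ± 22.2 CPM in controls and 99.1 ± 15.9 CPM in the libraries labelled knockout. It was -1.15 (SE 0.57) in neutrophils, with 583 ± 367 and 258 ± 79.2 CPM, and -0.39 (SE 0.64) in monocytes, with 590 ± 444 and 444 ± 321 CPM. Endothelial cells gave -0.14 (SE 0.75) and hepatocytes -0.38 (SE 0.59). None of these passed (adjusted p = 0.999 to 1).

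**Figure D1:**
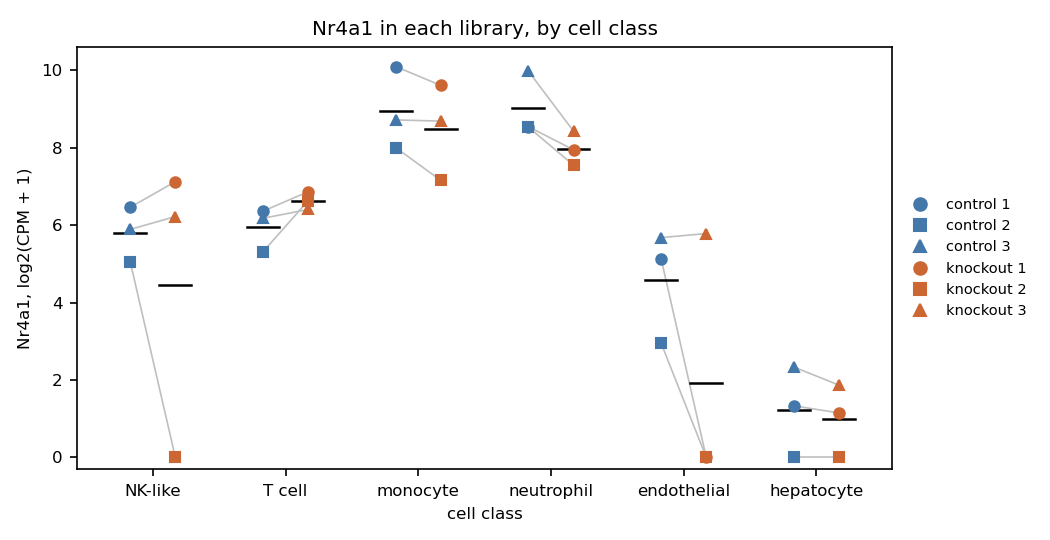
Nr4a1 per library in each class tested in all 6 libraries, as log2(CPM + 1), with a grey line joining the control and knockout library of the same number and a black dash at the mean of 3 libraries. In NK-like cells control and knockout overlap, and knockout 2 sits at 0.

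In NK-like cells, Serpine2, which encodes a secreted inhibitor of serine proteases (ENSMUSG00000026249), rose from 6.60 ± 2.91 to 43.3 ± 11.9 CPM (SD, n = 3 libraries each), a log2 fold change of 2.60 (SE 0.34, adjusted p = 0.0422, edgeR), and was higher in 3 of 3 same-numbered pairs. It rested on 15, 2 and 30 UMIs in controls 1, 2 and 3 and on 59, 6 and 32 in knockouts 1, 2 and 3. Among the 9 next genes by p, given as values, Crtam, an adhesion receptor of activated lymphocytes, had 48.2 ± 4.33 CPM in controls and 16.1 ± 2.79 CPM in the libraries labelled knockout (log2 fold change -1.49, SE 0.27), and Plcb4, a phospholipase C, had 51.2 ± 15.8 and 16 ± 3.12 CPM (-1.72, SE 0.33). Cdkn1a, the cell cycle inhibitor p21, had 15.6 ± 7.74 and 45.4 ± 19.3 CPM (1.52, SE 0.35), and Ccng1, like Cdkn1a a p53 target, had 30.7 ± 5.61 and 61.1 ± 4.40 CPM (0.96, SE 0.24). Klra5, an inhibitory receptor of the Ly49 family whose near-identical members make its count uncertain, gave 1.51 (SE 0.36), and Cd3e, a chain of the T cell receptor complex, gave 2.40 (SE 0.58). Rpp38, a subunit of ribonuclease P, gave 1.46 (SE 0.36), the carboxypeptidase gene Cpq gave -1.20 (SE 0.31), and Prss2, a trypsinogen of a family with close copies, gave -2.40 (SE 0.56). Their adjusted p were 0.475 for Crtam and Plcb4 and 1 for the others. For genes changed in NK-like cells, 1 of 8320 tested passed (1 higher, 0 lower) and 136 had an unadjusted p under 0.05. DESeq2 also called 1 gene, Serpine2 (adjusted p = 0.00117). The call was lost without any 1 of the 6 libraries: the adjusted p of Serpine2 in NK or ILC1 cells was 0.0916, 0.0623 and 0.803 without controls 1, 2 and 3, and 1, 0.12 and 0.117 without knockouts 1, 2 and 3. It was lost too with mixed clusters defined at 0.8 (adjusted p = 0.139), the value tried before 0.7 was used, where 0 of 7432 genes passed and 135 had an unadjusted p under 0.05. In clusters built without the 10 genes called under the block its adjusted p was 0.921, and with both libraries numbered 2 left out 0.199. The log2 fold change was 2.73, 2.36 and 2.51 in these 3 settings and 2.26 to 2.82 leaving out 1 library. In the largest NK cluster built without the 10 genes it was 2.77 (SE 0.45, adjusted p = 0.192), and with the block it passed there (2.53, adjusted p = 0.0132). The fold thus held, while the call without the block rests on the choice of clusters and on every library. Without knockout 2, 1 other gene passed, the T cell receptor gene Trgc2 (3.4), named here after its value was seen.

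With the replicate number as a block, 10 genes passed in NK-like cells, 7 higher and 3 lower. Higher in the libraries labelled knockout were Serpine2 (2.49), Cd3e (2.23), Klra5 (1.57), Cd3g (1.53), Cd3d (1.5), Trac (1.45) and Cdkn1a (1.45). Lower were Plcb4 (-1.60), Crtam (-1.51) and Ncr1 (-1.34), with adjusted p from 0.000947 to 0.019 over the 10. With mice as units and the same block only Serpine2 passed (2.43, adjusted p = 0.0175), and the other 9 calls were lost. Cd3g, Cd3d and Trac lay outside the rule for named genes and were named after their values were seen. Ncr1, the gene that carries Cre and 1 of the 12 markers that named the NK-like class, had 749, 626 and 650 CPM in controls 1, 2 and 3 and 160, 545 and 254 CPM in knockouts 1, 2 and 3, and without the block its log2 fold change was -1.17 (SE 0.36, adjusted p = 1). The Cd3e count was 36, 3 and 74 UMIs in controls and 164, 0 and 57 in the libraries labelled knockout, so it was higher in pairs 1 and 3 only. When NK-like cells were taken cell by cell, by a UMI of Ncr1 or Klrb1c and none of 6 genes of other types (3 of them Cd3 genes), 0 genes passed in edgeR without the block, 44 had an unadjusted p under 0.05, and Klra5 turned to -0.40.

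**Figure D2:**
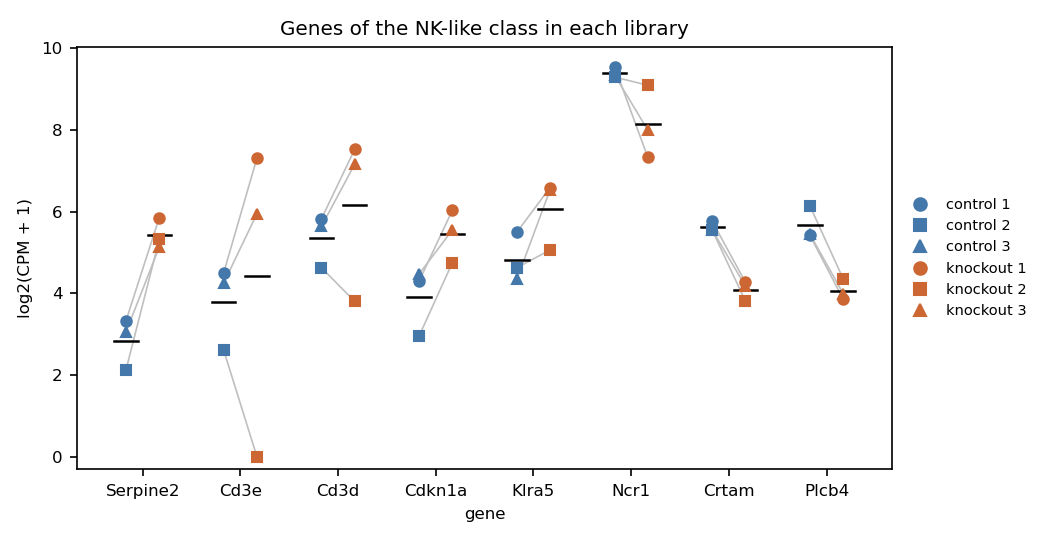
Serpine2, Cd3e, Cd3d, Cdkn1a, Klra5, Ncr1, Crtam and Plcb4 per library in NK-like cells, as log2(CPM + 1), with grey lines joining libraries of the same number and a black dash at the mean of 3 libraries. Serpine2 lies higher in the knockout library of all 3 pairs and Ncr1, Crtam and Plcb4 lie lower.

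Of 22 gene lists tested in NK-like cells, 8 passed, 5 of them upward (camera with a preset correlation). T and B cell genes, a list of background markers, rose (median log2 fold change 1.53, 6 of 9 members higher, adjusted p = 8.31e-06, and adjusted p = 0.52 with an estimated correlation). The members that carried it were Cd3e and Cd8a (1.80, SE 0.49), with Trac and Cd3d, while Ighm, Igkc and Trbc1 were not higher. In the same cells the hepatocyte background genes fell (-0.60, 16 of 16 lower, adjusted p = 0.00601, and adjusted p = 0.878 with an estimated correlation). Fgb, a fibrinogen chain, stood at -0.97 (SE 0.70) and Trf, transferrin, at -0.58 (SE 0.46). Genes of apoptosis and the p53 response rose (0.25, 14 of 18 higher, adjusted p = 5.79e-05, and adjusted p = 0.391 with an estimated correlation), led by Cdkn1a and Ccng1. Activating receptors and their adaptors fell (-0.12, 16 of 20 lower, adjusted p = 0.000132, and adjusted p = 0.391 with an estimated correlation), with Crtam and Ncr1 first by p. Inhibitory receptors and checkpoints rose (0.31, 12 of 16 higher, adjusted p = 0.00168, and adjusted p = 0.52 with an estimated correlation). Klra5 came first by p, and Entpd1, the ATP-degrading CD39, stood at 0.83 (SE 0.24). Markers of immature NK cells fell (-0.22, 9 of 15 lower, adjusted p = 0.00601, and adjusted p = 0.546 with an estimated correlation), among them Kit, the stem cell factor receptor, at -1.02 (SE 0.36) and Tcf7, a transcription factor of early lymphocytes, at -0.78 (SE 0.23). Targets of MYC and genes of ribosome biogenesis rose (0.17, 22 of 27 higher, adjusted p = 0.0272, and adjusted p = 0.52 with an estimated correlation). The nucleolar gene Ncl stood at 0.41 (SE 0.22) and Fbl, another, at 0.39 (SE 0.23). Heat shock genes rose (0.20, 12 of 12 higher, adjusted p = 0.0469, and adjusted p = 0.878 with an estimated correlation). The chaperone gene Hspb1 stood at 1.44 (SE 0.60) and Hspa1a at 0.55 (SE 0.39). Adjusted over the list alone, 4 T and B cell genes (Cd3e, Cd8a, Trac and Cd3d), 2 p53 genes (Cdkn1a and Ccng1), 2 inhibitory receptors (Klra5 and Entpd1) and 1 activating receptor (Crtam) passed and none of the other 4 lists, against 0 in each list over all genes tested. With an estimated correlation 0 of the 22 lists passed.

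Single libraries decided several of these calls. Without knockout 1, 6 of the 8 were lost (adjusted p = 0.13 to 0.955), leaving the activating receptors and immature NK markers, and without knockout 3 the inhibitory receptors, immature NK markers, ribosome biogenesis and heat shock genes were lost (adjusted p = 0.0539 to 0.483). Without control 3 the immature NK markers, ribosome biogenesis and hepatocyte genes were lost (adjusted p = 0.29 to 0.733), and the hepatocyte genes turned upward without control 3 (median 0.14) and without knockout 1 (0.11), without control 2 the heat shock genes (adjusted p = 0.952) and without knockout 2 the immature NK markers (adjusted p = 0.94). The number of lists that passed was 3 without knockout 1, 13 without knockout 2 and 4 without knockout 3. The median of the inhibitory receptors was -0.07 without knockout 1, that of heat shock genes 0.00 without knockout 1 and that of immature NK markers 0.05 without knockout 2. With mixed clusters defined at 0.8, 4 of the 8 calls were lost (adjusted p = 0.0618 to 0.575). In clusters built without the 10 genes 4 were lost (adjusted p = 0.0658 to 0.245), and the immature NK markers then had a median of 0.03. In cells taken one by one the test for inhibitory receptors pointed downward (median -0.03, adjusted p = 0.671), and the hepatocyte genes had a median of 0.73 (adjusted p = 0.513). The heat shock and ribosome biogenesis calls were lost there too (adjusted p = 0.194 and 0.16), as they were with hashtag multiplets removed (adjusted p = 0.0541 for both). The heat shock call was also lost with background genes left out (adjusted p = 0.0522), and the immature NK call with both libraries numbered 2 left out (adjusted p = 0.424). In cells taken one by one 5 lists passed, and the T and B cell genes, whose Cd3 members that rule excludes by name, had a median of -0.37 (adjusted p = 0.313).

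**Figure D3:**
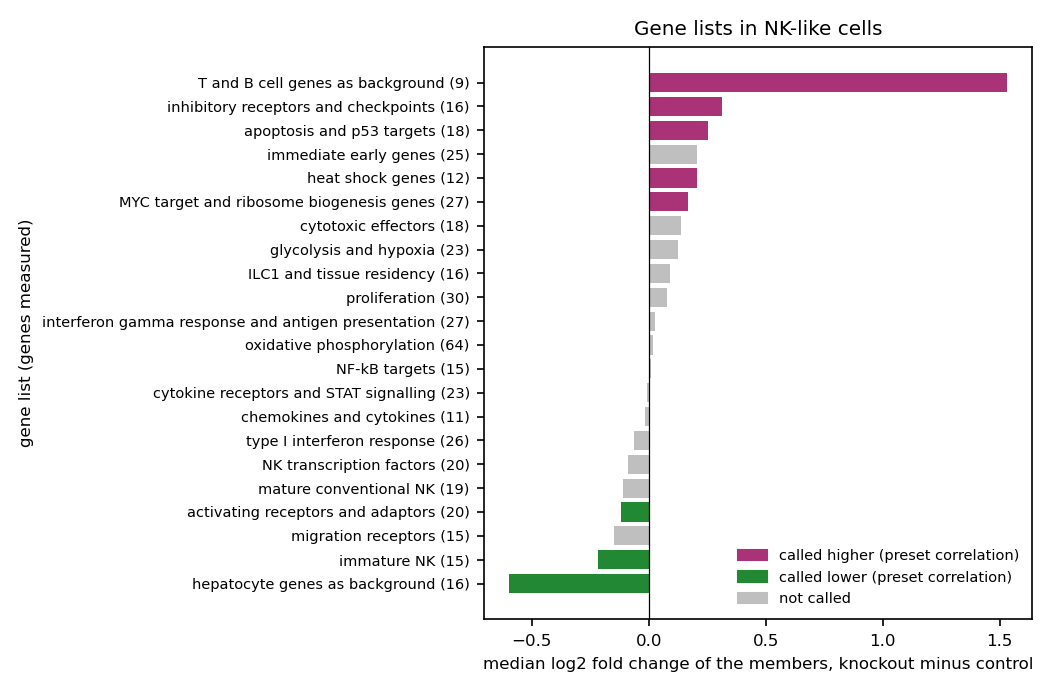
Median log2 fold change, libraries labelled knockout against control, of each gene list tested in NK-like cells, as bars from 0, purple for lists called higher and green for lists called lower at the preset correlation, grey for the others, and the number of measured members in brackets. The T and B cell genes lie farthest to the right at 1.53 and the hepatocyte genes farthest to the left at -0.60.

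The other 14 lists did not pass in NK-like cells without the block. With the replicate block 2 of them did. Migration receptors fell (median -0.15 and adjusted p = 0.00935 with it, 0.0892 without it, and adjusted p = 0.52 with an estimated correlation). Cytotoxic effectors rose with the block (0.07 and adjusted p = 0.00935 with it, 0.184 without it, and adjusted p = 0.878 with an estimated correlation). Without the block the pore-forming Prf1 stood at 0.40 (SE 0.23) and the granzyme Gzmm at -0.95 (SE 0.55). Glycolysis and hypoxia genes had a median of 0.12 (adjusted p = 0.14), with P4ha1 at 0.57 (SE 0.29) and Hk2 at -0.40 (SE 0.36). NK transcription factors had -0.09 (adjusted p = 0.297), with Tcf7 and with Ikzf2, which encodes Helios, at 0.85 (SE 0.34). Markers of mature conventional NK cells had -0.11 (adjusted p = 0.403), with the inhibitory Klrg1 at 0.67 (SE 0.30), and ILC1 and tissue residency markers had 0.09 (adjusted p = 0.563), with Ckb at 0.78 (SE 0.44) and the activation marker Cd69 at 0.68 (SE 0.42). Immediate early genes had 0.20 (adjusted p = 0.32), with Cd69 and Atf3 at 0.85 (SE 0.43). The test for type I interferon response genes pointed upward and their median was -0.06 (adjusted p = 0.32), with Ifi27l2a at 0.96 (SE 0.46) and Isg15 at 0.76 (SE 0.38), and interferon gamma response genes had 0.03 (adjusted p = 0.412), with Cxcl10 at 0.91 (SE 0.41) and Gbp3 at 0.37 (SE 0.30). Proliferation genes had 0.08 (adjusted p = 0.403), with Cenpf at -0.48 (SE 0.36) and Mcm5 at 0.44 (SE 0.34). The test for NF-kB targets pointed downward and their median was 0.01 (adjusted p = 0.517), with Traf1 at -0.37 (SE 0.30) and Relb at -0.32 (SE 0.30). Oxidative phosphorylation genes had 0.02 (adjusted p = 0.58), with Ndufa5 at 0.33 (SE 0.29) and Atp5g1 at 0.29 (SE 0.25). Cytokine receptors and STAT genes had -0.01 (adjusted p = 0.58), with Il18r1 at -0.34 (SE 0.24) and Socs3 at 0.57 (SE 0.43), and chemokines and cytokines had -0.02 (adjusted p = 0.73), with Ltb at -0.41 (SE 0.28) and Flt3l at 0.36 (SE 0.27).

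NK-like cells made up 17.37%, 39.56% and 8.28% of the blood cell classes in controls 1, 2 and 3 and 4.50%, 36.27% and 5.48% in knockouts 1, 2 and 3, from 306, 161 and 623 and from 110, 37 and 179 cells. The share was lower in the library labelled knockout in 3 of 3 same-numbered pairs. In pair 3 this came from 1 mouse: by the hashtags the 3 control mice had 4.75%, 5.67% and 20.21%, and the 2 mice of knockout 3 had 6.75% and 4.31%. The group means were 21.73% ± 16.09 and 15.42% ± 18.07 (SD, n = 3 libraries each), a difference of -6.32 percentage points that was smaller than the spread between libraries (p = 0.5, exact two-sided permutation test, smallest possible p 0.1). Within pairs the exact test gave its smallest possible p, 0.25. Without control 2 the difference turned to 2.60 points, and without knockout 2 it was -16.74 points, without knockout 1 -0.86, without knockout 3 -1.35 and without control 3 -13.04. When the clusters were built without the 10 genes that passed under the block, among them the NK marker Ncr1, the difference was -5.52 points. The labels name no sorting gate and describe enzymatic dissociation, and the shares are those of the cells recovered by it.

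A conventional NK subset, named by markers such as S1pr5, Itgam and Zeb2, held 13.45% ± 0.80 of the NK-like cells in controls and 12.55% ± 6.13 in the libraries labelled knockout (difference -0.90 points, p = 0.9, exact two-sided permutation test, n = 3 libraries each, smallest possible p 0.1). The difference turned to 0.38 points without knockout 1 and to 1.32 without knockout 2, and it was -4.40 without knockout 3. An ILC1 subset, whose leading genes include Cxcr6 and also Cd3g, Cd3e and Cd3d, held 11.60% ± 7.05 and 14.64% ± 10.36 (difference 3.05 points, p = 0.6, same exact test). Since Cd3 genes differed between the groups, the subset was built again without the 10 genes, and the difference was then -0.18 points. That NK class also took in a proliferating mixed cluster of T and NK cells. Over its largest NK cluster alone the ILC1 share was 18.5%, 4.58% and 18.9% in controls 1, 2 and 3 and 22.83%, 2.86% and 22.62% in knockouts 1, 2 and 3. It was thus higher in pairs 1 and 3 and lower in pair 2, as in the first clusters, and the Cd3 genes need not have made the difference. Without control 2 the ILC1 difference was -0.89 points and without knockout 3 it was -0.24. The other 4 of 6 subclusters had under 3 detected markers and stayed unnamed. Of the 16 named classes, 0 differed in their share of all kept cells in edgeR on cell numbers, and 1, megakaryocytes or platelets, had an unadjusted p under 0.05. The exact permutation test of each class gave an adjusted p of 1 throughout. Monocytes had the largest difference of mean shares, 6.80 points more in the libraries labelled knockout (exact two-sided permutation p = 0.3).

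**Figure D4:**
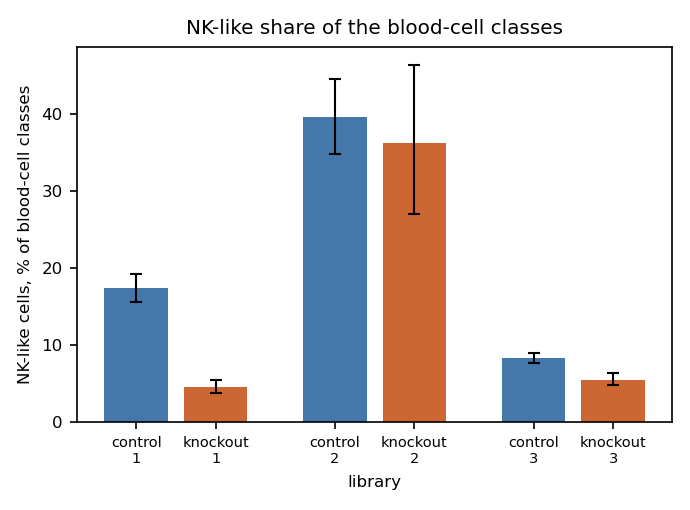
NK-like cells as a percentage of the blood cell classes in each library, with bars from 0 and 95% exact binomial intervals that cover counting error only. The knockout bar is the lower of each same-numbered pair, and both bars of pair 2 lie above those of the other 2 pairs.

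In T cells, several single genes of cytotoxic cells and of chemokines were lower in the libraries labelled knockout once the replicate number was a block. Gzma and Gzmk, which encode granzymes, gave -1.46 (adjusted p = 2.39e-05) and -1.24 (adjusted p = 3.61e-05), and the chemokine genes Ccl4 and Ccl3 gave -1.44 (adjusted p = 5.5e-06) and -1.29 (adjusted p = 1.21e-05). The fractalkine receptor gene Cx3cr1 gave -1.48 (adjusted p = 7.53e-05). Atf3, a stress-induced transcription factor, was higher (0.88, adjusted p = 0.0268). Chosen after their values were seen, Klrg1 (-1.05), Zeb2 (-1.18) and Ncr1 (-1.62) were also lower, and Il2ra (0.89), the interleukin 2 receptor alpha chain, and Id3 (0.94) were also higher. The block called 37 T cell genes, 9 higher and 28 lower, of which albumin (Alb, -1.56), fibrinogen (Fgb, -1.70) and other hepatocyte transcripts were part. With mice as units and the same block only Alb passed in T cells (-1.65, adjusted p = 0.00781). All the other calls named here were then lost, with an adjusted p of 0.562 for Gzma in T cells and 0.54 for Ccl4 in T cells. Without the block 0 of 10559 genes passed in edgeR, 178 had an unadjusted p under 0.05, DESeq2 called 0, and the log2 fold changes were -1.40 (SE 0.48) for Gzma, -1.28 (SE 0.44) for Gzmk, -1.38 (SE 0.42) for Ccl4, -1.18 (SE 0.37) for Ccl3 and -1.44 (SE 0.33) for Cx3cr1. Gzmk turned to 0.04 without control 3. The number of T cell genes that passed was 38 without knockout 3 (2 higher, 36 lower). Among the 36 were hepatocyte transcripts such as Mup3, Fabp1, Apoa1 and Alb, and the Y chromosome genes Kdm5d, Eif2s3y, Uty and Ddx3y, and no gene of cytotoxic cells or chemokines. Without knockout 3, knockout 1 holds most T cells of its group, and Y genes were read in 0.96% of its cells. The Y gene calls thus cannot be read apart from the sex of the libraries. The number of T cell genes that passed was 4 without control 3 (Ncr1, Frmd4a, Clnk and Abi3bp, all lower), 2 without control 2 (the immunoglobulin genes Igha and Jchain, lower) and 1 without control 1 (Klrh1, higher), all named after their values were seen. The T cell class held 360, 61 and 3290 cells in controls and 690, 12 and 1119 in the libraries labelled knockout. Its largest cluster was number 11, of naive and memory genes such as Lef1 and Il7r, in controls 1 and 2 and knockouts 1 and 3, number 14, of Cd8a, Gzmk and Gzmb, in control 3, and number 4, led by nuclear transcripts such as Bcl11b and Themis, in knockout 2.

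Of the lists tested in T cells, 9 passed. Cytotoxic effectors fell (median log2 fold change -0.09, 12 of 17 lower, adjusted p = 0.018, and adjusted p = 0.79 with an estimated correlation), and chemokines and cytokines fell (-0.09, 11 of 17 lower, adjusted p = 0.0286, and adjusted p = 0.778 with an estimated correlation), with Ccl4 and Ccl3 passing when adjusted over the list alone. Migration receptors fell (-0.24, 12 of 17 lower, adjusted p = 0.00363, and adjusted p = 0.729 with an estimated correlation), with Cx3cr1 and the sphingosine phosphate receptor S1pr5 (-1.77, SE 0.51) passing over the list alone. Targets of MYC and genes of ribosome biogenesis rose (0.32, 25 of 28 higher, adjusted p = 1.46e-05, and adjusted p = 0.729 with an estimated correlation). Srm stood at 0.61 (SE 0.30) and Nop16 at 0.58 (SE 0.30). Glycolysis and hypoxia genes rose (0.33, 20 of 23 higher, adjusted p = 0.00112, and adjusted p = 0.729 with an estimated correlation), with P4ha1 at 0.63 (SE 0.29) and Pgam1 at 0.52 (SE 0.27). Immediate early genes rose (0.19, 22 of 29 higher, adjusted p = 0.0174, and adjusted p = 0.81 with an estimated correlation). Atf3 stood at 0.86 (SE 0.30) and Nr4a3 at 0.61 (SE 0.29). Targets of NF-kB rose (0.14, 12 of 16 higher, adjusted p = 0.0286, and adjusted p = 0.786 with an estimated correlation). Relb stood at 0.53 (SE 0.29) and Cd83 at 0.50 (SE 0.38). Markers of other cells moved as well: hepatocyte genes fell (-0.91, 24 of 24 lower, adjusted p = 1.68e-06, and adjusted p = 0.786 with an estimated correlation). Fgb stood at -1.58 (SE 0.44, passing over the list alone) and Hpx at -1.21 (SE 0.43). Macrophage and neutrophil genes rose (0.54, 4 of 4 higher, adjusted p = 0.0181, and adjusted p = 0.729 with an estimated correlation). Ctss stood at 0.52 (SE 0.26) and S100a8 at 1.44 (SE 0.73). With the replicate block 5 more lists passed. Naive and memory genes rose (0.19, adjusted p = 0.0362, and adjusted p = 0.79 with an estimated correlation). Heat shock genes rose (0.26, adjusted p = 0.0238, and adjusted p = 0.886 with an estimated correlation). Cytokine receptors rose (0.13, adjusted p = 0.0297, and adjusted p = 0.79 with an estimated correlation). Exhaustion genes, Ccl4 and Ccl3 among them, fell (-0.31, adjusted p = 0.0297, and adjusted p = 0.786 with an estimated correlation). Oxidative phosphorylation genes fell (-0.05, adjusted p = 0.0478, and adjusted p = 0.965 with an estimated correlation). The ribosome biogenesis call was kept without any 1 library. Lost were 4 calls without knockout 1 (hepatocyte, glycolysis, immediate early and NF-kB genes, adjusted p = 0.0727 to 0.667), 4 without control 3 (hepatocyte genes, cytotoxic effectors, migration receptors and NF-kB targets, adjusted p = 0.123 to 0.893) and 3 without knockout 3 (glycolysis, immediate early genes and migration receptors, adjusted p = 0.0541 to 0.64). Without control 1 the cytotoxic effectors and the macrophage and neutrophil genes were lost (adjusted p = 0.166 to 0.18), without control 2 the immediate early genes and NF-kB targets (adjusted p = 0.404 to 0.62) and without knockout 2 the cytotoxic effectors and chemokines (adjusted p = 0.309 to 0.334). The median of the cytotoxic effectors was 0.04 without control 3 and that of the chemokines 0.00 without knockout 2. Without knockout 1 the test for hepatocyte genes pointed upward beside a median of -0.03. The chemokine call was lost as well with mice as units (adjusted p = 0.0835), in stricter cells (adjusted p = 0.152) and, with the NF-kB call, with both libraries numbered 2 left out (adjusted p = 0.0877 to 0.0897). With no filter on low counts 4 calls were lost (cytotoxic effectors, chemokines, NF-kB targets and macrophage and neutrophil genes, adjusted p = 0.0506 to 0.108).

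**Figure D5:**
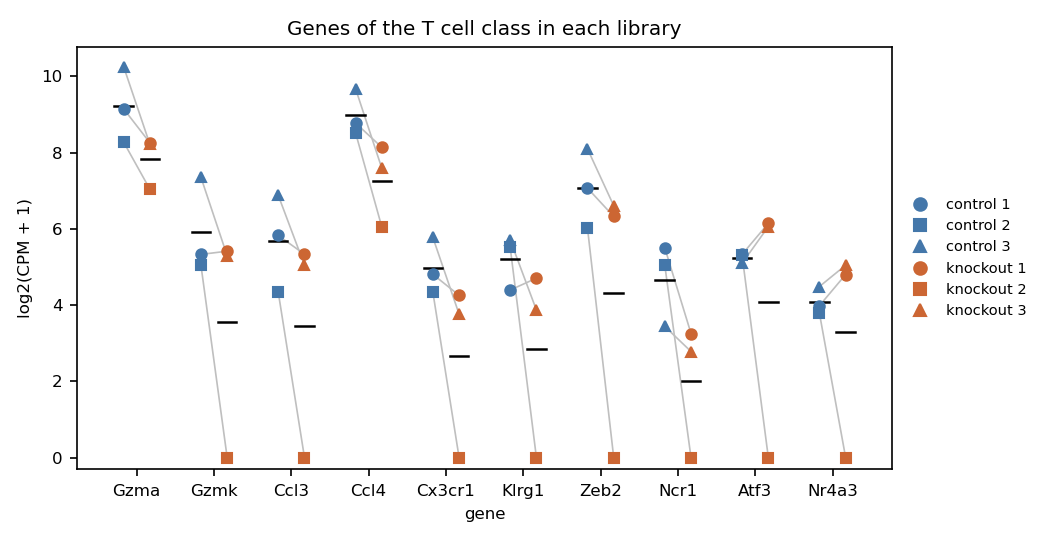
Gzma, Gzmk, Ccl3, Ccl4, Cx3cr1, Klrg1, Zeb2, Ncr1, Atf3 and Nr4a3 per library in T cells, as log2(CPM + 1), with grey lines joining libraries of the same number and a black dash at the mean of 3 libraries. Knockout 2, which holds 12 T cells, sits at 0 for several genes.

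In monocytes, S100a9 and S100a8, which encode the calprotectin subunits abundant in neutrophils, had 13.4 ± 6.92 and 9.85 ± 9.25 CPM in controls and 391 ± 420 and 762 ± 1100 CPM in the libraries labelled knockout (log2 fold changes 5.05, SE 1.10, and 5.78, SE 1.30). Under the block S100a9 was higher (4.26, adjusted p = 0.00629), as was the chemokine gene Cxcl3, named after its value was seen, for which no fold is given because the controls held none of its UMIs. The neutrophil activation list, of which both S100 genes are members, rose (0.60, 11 of 12 higher, 2 passing over the list alone, adjusted p = 4.15e-06, and adjusted p = 0.456 with an estimated correlation). Inflammatory macrophage genes rose (0.36, 10 of 12 higher, adjusted p = 0.00899, and adjusted p = 0.729 with an estimated correlation), with the cytokine genes Il6 (2.62, SE 0.61) and Ccl2 (3.24, SE 1.05) and, named after its value was seen, Il1a passing over the list alone. Immunosuppressive macrophage genes rose (0.84, 6 of 7 higher, adjusted p = 0.0348, and adjusted p = 0.729 with an estimated correlation). Arg1, arginase 1, stood at 2.16 (SE 1.22) and the angiogenic factor Vegfa at 0.88 (SE 0.47). Glycolysis and hypoxia genes rose (0.40, 24 of 24 higher, adjusted p = 6.69e-07, and adjusted p = 0.729 with an estimated correlation). Ero1a, an oxidase of the endoplasmic reticulum, stood at 1.17 (SE 0.56), and Vegfa is a member here too. Interferon gamma response genes fell (-0.14, 21 of 30 lower, adjusted p = 0.0286, and adjusted p = 0.869 with an estimated correlation). Iigp1 stood at -1.01 (SE 0.65) and Cxcl10 at -0.96 (SE 0.69). The hepatocyte background genes fell in the same cells (-0.80, 22 of 23 lower, adjusted p = 1.68e-06, and adjusted p = 0.786 with an estimated correlation). Fgg stood at -1.40 (SE 0.54) and Fgb at -1.43 (SE 0.57), and with the replicate block the erythroid genes rose (1.31, adjusted p = 0.0414, and adjusted p = 0.918 with an estimated correlation). No monocyte gene of 8895 passed in edgeR without the block, 138 had an unadjusted p under 0.05, and DESeq2 called 0. Without knockout 1, S100a9 (5.68) and Cxcl3 passed, and the calls of the inflammatory and hepatocyte genes were lost (adjusted p = 0.157 to 0.488). Lost too were the interferon gamma and hepatocyte genes without control 3 (adjusted p = 0.231 to 0.91). So were the interferon gamma and immunosuppressive genes without knockout 2 (adjusted p = 0.317 to 0.866). So were the immunosuppressive genes without control 1 (adjusted p = 0.115). So were the inflammatory genes without control 2 (adjusted p = 0.44) and the interferon gamma genes without knockout 3 (adjusted p = 0.155). The inflammatory genes had a median of -0.19 without knockout 1, and the interferon gamma genes turned upward without control 3. With doublets kept 4 of the 6 calls were lost (adjusted p = 0.27 to 0.927), and in clusters built without the 10 genes 5 (adjusted p = 0.0965 to 0.77). The glycolysis call, kept without any 1 library, was among them. Its test pointed downward with doublets kept (median 0.04, adjusted p = 0.927) and in clusters built without the 10 genes (adjusted p = 0.703). It was lost in stricter cells (0.18, adjusted p = 0.307) and with both libraries numbered 2 left out (0.13, adjusted p = 0.125). The inflammatory genes turned to -0.16 in clusters built without the 10 genes (adjusted p = 0.77), and the immunosuppressive genes to -0.01 with doublets kept (adjusted p = 0.828). The inflammatory call was lost with mice as units too (adjusted p = 0.308), where S100a9 passed (4.33) and Cxcl3 did not. In stricter cells 3 calls were lost (adjusted p = 0.204 to 0.595). The immunosuppressive call was also lost with no filter on low counts (adjusted p = 0.0947) and with both libraries numbered 2 left out (adjusted p = 0.0897).

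In neutrophils, Spp1, which encodes the secreted phosphoprotein osteopontin, had 46.1 ± 26.7 CPM in controls and 1360 ± 1950 CPM in the libraries labelled knockout (4.96, SE 1.33, adjusted p = 0.999 in edgeR). It was the 1 gene called by DESeq2 (4.96, adjusted p = 0.00464) and the 1 called under the block (3.63, adjusted p = 0.0119), where the neutrophils of the libraries numbered 3 correlated at only 0.053. Without the block edgeR called 0 of 3639 genes, and 34 had an unadjusted p under 0.05. Immediate early genes, a list without Nr4a1, fell (-0.61, 22 of 24 lower, adjusted p = 4.83e-05, and adjusted p = 0.729 with an estimated correlation). Fosb stood at -1.52 (SE 0.79), while Rgs1, a regulator of G protein signalling, stood at 2.27 (SE 0.88). Targets of NF-kB fell (-0.57, 13 of 16 lower, adjusted p = 0.00019, and adjusted p = 0.729 with an estimated correlation). Nfkb2 stood at -1.45 (SE 0.60) and Bcl2a1b, of a family with close copies, at -1.34 (SE 0.60). Proliferation genes rose (1.04, 12 of 14 higher, adjusted p = 0.00131, and adjusted p = 0.79 with an estimated correlation). Ube2c stood at 1.84 (SE 1.17) and Nusap1 at 1.90 (SE 1.23). Glycolysis and hypoxia genes rose (0.47, 17 of 21 higher, adjusted p = 0.00541, and adjusted p = 0.729 with an estimated correlation). Bnip3 stood at 1.34 (SE 0.81) and Aldoa at 0.75 (SE 0.46). Type I interferon response genes rose (0.28, 16 of 18 higher, adjusted p = 0.0152, and adjusted p = 0.729 with an estimated correlation). Ifit3 stood at 1.01 (SE 0.57) and Usp18 at 1.28 (SE 0.92). Lipid-associated macrophage genes rose (0.46, 7 of 8 higher, adjusted p = 0.0237, and adjusted p = 0.729 with an estimated correlation), with Spp1, which passed over the list alone, and Ctsb at 0.85 (SE 0.49). The hepatocyte background genes fell (-1.11, 14 of 14 lower, adjusted p = 6.69e-07, and adjusted p = 0.729 with an estimated correlation). Apoc1 stood at -1.73 (SE 1.05) and Serpina1c, of a family with close copies, at -1.57 (SE 0.81). With the replicate block the test for immunosuppressive macrophage genes pointed upward beside a median of -0.01 (adjusted p = 0.0414, and adjusted p = 0.79 with an estimated correlation). Lost were the immediate early, NF-kB, proliferation and hepatocyte calls without knockout 1 (adjusted p = 0.0586 to 0.714). So were the proliferation, glycolysis and NF-kB calls without control 3 (adjusted p = 0.0512 to 0.117). So were the interferon and lipid-associated calls without control 1 (adjusted p = 0.15 to 0.924). So were the glycolysis and interferon calls without knockout 2 (adjusted p = 0.258 to 0.601) and the lipid-associated call without knockout 3 (adjusted p = 0.127). The median of the proliferation genes turned to -0.20 without knockout 1, and that of the interferon genes to -0.04 without control 1. The interferon and lipid-associated calls were lost with mice as units (adjusted p = 0.194 and 0.248), where Spp1 in neutrophil cells did not pass either (3.22, adjusted p = 0.655). The same 2 calls were lost with doublets kept (adjusted p = 0.2 and 0.0869, the interferon median then -0.04). In stricter cells these and the glycolysis call were lost (adjusted p = 0.0635 to 0.494), and with both libraries numbered 2 left out the interferon and glycolysis calls (adjusted p = 0.0538 to 0.125). Cluster 12, of granule genes of immature neutrophils such as Camp and Elane, held 28.95%, 2.94% and 0% of the neutrophils in controls 1, 2 and 3 and 25%, 0% and 8.11% in knockouts 1, 2 and 3.

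In hepatocytes, transcripts of mature liver metabolism fell (-0.17, 18 of 20 lower, adjusted p = 0.00141, and adjusted p = 0.786 with an estimated correlation). Their first members by p were the cytochrome P450 genes Cyp2e1, with 19.9 ± 17.6 CPM in controls and 5.49 ± 5.04 CPM in the libraries labelled knockout (-2.66, SE 0.67, passing over the list alone), and Cyp1a2, with 3.71 ± 4.68 and 0.621 ± 0.625 CPM (-2.33, SE 0.70). Interferon gamma response and antigen presentation genes rose (0.28, 15 of 24 higher, adjusted p = 2.25e-05, and adjusted p = 0.729 with an estimated correlation). The GTPase gene Igtp stood at 1.09 (SE 0.45) and the immunoproteasome gene Psmb8 at 1.22 (SE 0.57). Ligands of NK receptors rose (0.24, 7 of 10 higher, adjusted p = 0.00899, and adjusted p = 0.729 with an estimated correlation). Raet1e, an NKG2D ligand, stood at 0.74 (SE 0.44) and B2m, the class I light chain, at 0.94 (SE 0.60). Proliferation genes fell (-0.12, 24 of 30 lower, adjusted p = 0.0174, and adjusted p = 0.786 with an estimated correlation). Top2a stood at -0.31 (SE 0.24) and Aurkb at -0.29 (SE 0.27). Glycolysis and hypoxia genes fell (-0.11, 20 of 23 lower, adjusted p = 0.047, and adjusted p = 0.79 with an estimated correlation), with Pkm at -0.25 (SE 0.24) and Pdk1 at -0.26 (SE 0.26). General hepatocyte genes rose (0.17, 18 of 25 higher, adjusted p = 0.0106, and adjusted p = 0.869 with an estimated correlation). The acute phase gene Hp stood at 2.56 (SE 0.92), and Cyp2e1, the 1 member that passed over the list alone, was lower. The call of the general hepatocyte genes was lost under the block (adjusted p = 0.127). Erythroid background genes fell (-4.62, 3 of 3 lower, all 3 passing over the list alone, adjusted p = 0.00131, and adjusted p = 0.729 with an estimated correlation). The alpha globin gene Hba-a1 stood at -5.29 (SE 1.59) and its near-identical copy Hba-a2 at -4.62 (SE 1.48). Without control 3 Hba-a1 in hepatocytes and Hba-a2 in hepatocytes turned to 1.56 and 2.02. The block called 24 genes, 2 higher and 22 lower, among them Cyp2e1 (-3.04), Cyp1a2 (-2.60) and, named after their values were seen, Pck1 (-1.34), the key enzyme of gluconeogenesis, and Tat (-1.34), tyrosine aminotransferase. With mice as units and the same block 0 hepatocyte genes passed, and Cyp2e1 in hepatocyte cells had -3.38 (adjusted p = 0.991). Without the block 0 of 11553 passed in edgeR, 102 had an unadjusted p under 0.05, and DESeq2 called 0. The number was 2 without control 1 (Hba-a1 and Hba-a2), 2 without control 3 (S100a6 and Saa2) and 5 without knockout 1 (Spp1, Hp and Rbp2 higher, Hmga2 and Gm47283 lower), named after their values were seen. Most hepatocytes came from cluster 10 in control 3 and from cluster 8 in the other 5 libraries. Cluster 10 held 19.25%, 5.56% and 56.56% of hepatocytes in controls 1, 2 and 3. In knockouts 1, 2 and 3 it held 5.88%, 8.33% and 40.48%. At Leiden resolution 2, a hepatocyte cluster of 605 cells shared leading genes such as Lgals2, Fabp6 and H19 with a tumour hepatocyte cluster. Another, of 650 cells, was led by Akr1c6, Bhmt and Fabp1. The class may thus hold tumour-like cells, and whether its mix gives the falls of metabolism genes was not tested. Of the 7 list calls, 4 were lost without control 1 (interferon gamma, proliferation, general hepatocyte and NK ligand genes, adjusted p = 0.166 to 0.805), 4 without control 2 (proliferation, glycolysis, general hepatocyte and NK ligand genes, adjusted p = 0.125 to 0.798), 3 without control 3 (glycolysis, erythroid and metabolism genes, adjusted p = 0.237 to 0.842), 4 without knockout 1 (interferon gamma, glycolysis, erythroid and metabolism genes, adjusted p = 0.0816 to 0.667), 4 without knockout 2 (interferon gamma, glycolysis, general hepatocyte and NK ligand genes, adjusted p = 0.124 to 0.937) and 2 without knockout 3 (proliferation and general hepatocyte genes, adjusted p = 0.129 to 0.351). Several of these turned. With both libraries numbered 2 left out the general hepatocyte genes were called lower (-0.20, adjusted p = 0.000106). Their test also pointed downward without knockout 2 (-0.07, adjusted p = 0.124) and in clusters built without the 10 genes (-0.22, adjusted p = 0.38). The NK ligands turned downward without knockout 2 (-0.09, adjusted p = 0.937), with both libraries numbered 2 left out (-0.25, adjusted p = 0.617), in stricter cells (-0.07, adjusted p = 0.82) and in clusters built without the 10 genes (-0.24, adjusted p = 0.861). The median of the interferon gamma genes was -0.36 without knockout 1, -0.08 without knockout 2, -0.08 in stricter cells and -0.15 in clusters built without the 10 genes. With both libraries numbered 2 left out 5 of the 7 calls were lost or turned. These were the general hepatocyte and NK ligand genes above, the interferon gamma genes (-0.10, adjusted p = 0.778), the proliferation genes (adjusted p = 0.216) and the glycolysis genes (median 0, adjusted p = 0.874). The proliferation genes had a median of 0.06 with mice as units (adjusted p = 0.308). With mice as units 5 of the 7 calls were lost (interferon gamma, proliferation, glycolysis, general hepatocyte and NK ligand genes, adjusted p = 0.193 to 0.619), leaving the metabolism and erythroid genes. In stricter cells 4 were lost (adjusted p = 0.217 to 0.82), and the glycolysis and NK ligand calls with no filter on low counts (adjusted p = 0.118 for both). The glycolysis call was lost with median-of-ratios scaling (adjusted p = 0.05) and, by its adjustment over more classes, at an adjusted p of 0.0511. The erythroid genes turned to 1.75 without control 3. In clusters built without the 10 genes 6 of the 7 calls were lost (adjusted p = 0.0931 to 0.861).

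In endothelial cells, proliferation genes fell (-0.31, 10 of 11 lower, adjusted p = 0.000434, and adjusted p = 0.543 with an estimated correlation). The topoisomerase gene Top2a stood at -1.52 (SE 0.50) and Mki67 at -1.30 (SE 0.54). Genes of endothelial activation and angiogenesis fell (-0.31, 8 of 11 lower, adjusted p = 0.0174, and adjusted p = 0.729 with an estimated correlation). Esm1, a marker of sprouting vessels, had 44.6 ± 21.7 CPM in controls and 14.5 ± 15.6 CPM in the libraries labelled knockout (-3.31, SE 0.86, passing over the list alone), and Vwf, von Willebrand factor, gave -1.07 (SE 0.69). Type I interferon response genes rose (0.21, 16 of 18 higher, adjusted p = 0.0082, and adjusted p = 0.786 with an estimated correlation). Ifit2 stood at 0.60 (SE 0.45) and Ifit3 at 0.58 (SE 0.44). Oxidative phosphorylation genes rose (0.20, 56 of 63 higher, adjusted p = 0.0174, and adjusted p = 0.915 with an estimated correlation). Ndufb7 stood at 0.64 (SE 0.46) and Ndufv2 at 0.57 (SE 0.42), and without knockout 3 the oxidative genes fell (-0.54, adjusted p = 0.000354). Glycolysis and hypoxia genes rose (0.23, 14 of 17 higher, adjusted p = 0.0181, and adjusted p = 0.786 with an estimated correlation). Mif stood at 0.91 (SE 0.53) and Eno1 at 0.72 (SE 0.42). Targets of MYC and genes of ribosome biogenesis rose (0.26, 13 of 15 higher, adjusted p = 0.0468, and adjusted p = 0.79 with an estimated correlation). Gnl3 stood at 0.55 (SE 0.38) and Nop58 at 0.46 (SE 0.39), and the ribosome biogenesis call was lost under the block (adjusted p = 0.0988). With the replicate block the sinusoidal identity genes rose (0.23, adjusted p = 0.0337, and adjusted p = 0.79 with an estimated correlation). The erythroid background genes fell (-0.85, adjusted p = 2.26e-05, and adjusted p = 0.915 with an estimated correlation). Immediate early genes fell (-0.14, adjusted p = 0.0414, and adjusted p = 0.918 with an estimated correlation). In edgeR 0 of 5938 genes passed with or without the block, with 106 and 23 at an unadjusted p under 0.05, and DESeq2 called 0, while without control 2 the immunoglobulin genes Igha and Jchain, named after their values were seen, were lower. The proliferation call was kept without any 1 library, but in clusters built without the 10 genes it turned upward (0.21, adjusted p = 0.979), and the angiogenesis call was lost (adjusted p = 0.921). Lost were the oxidative, glycolysis, ribosome and angiogenesis calls without control 1 (adjusted p = 0.0574 to 0.975). So were the interferon, oxidative, glycolysis and ribosome calls without control 2 (adjusted p = 0.122 to 0.652). So were the glycolysis, ribosome and angiogenesis calls without knockout 3 (adjusted p up to 0.89), and the ribosome and angiogenesis calls without control 3 (adjusted p = 0.0512 to 0.229). Lost as well were the interferon call without knockout 1 (adjusted p = 0.911) and the glycolysis call without knockout 2 (adjusted p = 0.126). Without knockout 3 the glycolysis genes had a median of -0.27 and the ribosome genes -0.25. With mice as units the interferon call was lost (adjusted p = 0.0561), and with no filter on low counts the interferon, oxidative and ribosome calls (adjusted p = 0.108 to 0.181). With both libraries numbered 2 left out the oxidative, glycolysis and ribosome calls were lost (adjusted p = 0.275 to 0.856). The glycolysis call was lost in stricter cells (adjusted p = 0.205), and the ribosome call when adjusted over more classes (adjusted p = 0.0502).

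For genes changed in other classes, 0 of 40584 gene tests passed over the 5 classes in edgeR, with 475 at an unadjusted p under 0.05 and 1 by DESeq2, against 64 under the block (14 higher, 50 lower). Of 82 tests of lists 35 passed, 20 upward and 15 downward, and 43 passed under the block. With an estimated correlation 0 passed. Leaving out 1 library gave 3, 4 and 6 genes without controls 1, 2 and 3 and 7, 0 and 38 without knockouts 1, 2 and 3.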

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

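The choice to compare classes for Nr4a1 was made only after its values were seen. Nr4a1, the gene floxed in these mice, was higher in the T cells of the library labelled knockout in 3 of 3 same-numbered pairs, and lower in its neutrophils and monocytes in 3 of 3 pairs, and this opposite movement of every pair is why it stands here. The log2 fold changes were 0.50 (SE 0.27) in T cells, -1.15 (SE 0.57) in neutrophils and -0.39 (SE 0.64) in monocytes, so that T cells differed from neutrophils by 1.65 and from monocytes by 0.89. The difference was not tested, and none of the 3 changes passed alone. No explanation, technical or biological, was tested for it.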

How the results depend on the processing

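Alternatives chosen after seeing the data were the removal of hashtag multiplets, mixed clusters defined at 0.8 (the value tried first, before 0.7), clusters built without the 10 genes called under the block, both libraries numbered 2 left out, every class with 2 or more libraries per group, and stricter cells in those classes. The planned stricter cells gave no value for the other classes, since knockout 2 then held under 10 cells of each. In NK-like cells, Serpine2 stayed the 1 gene with mice as units, median-of-ratios scaling, stricter cells, doublets kept, DESeq2 and background genes left out. The count of genes was 10 with the replicate block and 25 with no filter, and it was 0 in cells taken one by one, with mixed clusters at 0.8, in clusters without the 10 genes and with both libraries numbered 2 left out (edgeR, with 44, 135, 159 and 323 genes at an unadjusted p under 0.05), and 0 to 1 leaving out 1 library. Of the lists in NK-like cells, 8 passed, against 5 in cells taken one by one, 5 with background genes left out, 4 with mixed clusters at 0.8, 0 with an estimated correlation and 3 to 13 leaving out 1 library. In the other classes the 0 genes of edgeR became 64 with the replicate block, 2 with mice as units, 86 with no filter, 2 in every class with 2 or more libraries per group, 1 with DESeq2 and 0 to 38 leaving out 1 library. The 2 with mice as units were S100a9 in monocytes (4.33) and Alb in T cells (-1.65), and the 2 with more classes were Igkv8-24 and Ighg1 in B cells, named after their values were seen. The 35 lists became 23 in clusters without the 10 genes, where macrophages took the place of T cells (9 of the 35 calls), 35 with doublets kept, where macrophages and tumour hepatocytes took the place of endothelial cells and hepatocytes, 69 of 181 with more classes, 0 with an estimated correlation and 27 to 37 leaving out 1 library. The cause of these changes was not tested, except that fewer libraries and more genes or classes enter by construction. Leaving out any 1 library also made the share of libraries with Xist differ between the groups. Nr4a1 in NK-like cells ran from -0.22 to 0.83 leaving out 1 library, turning without knockout 1, and the NK-like share difference from -16.74 to 2.60 points, turning without control 2. The conventional NK share difference of -0.90 points turned to 0.23 with mice as units, 0.44 at Leiden resolution 2, 0.49 with mixed clusters at 0.8 and 1.74 with both libraries numbered 2 left out, and ran from -4.40 to 1.32 leaving out 1 library. The cause of these turns was not tested. Class shares that differ stayed at 0 (edgeR) in every setting, 0 to 0 leaving out 1 library. Among the lists of NK-like cells and of the 5 classes with all 6 libraries, the replicate block changed no call other than those given beside the results. In the classes with fewer libraries it changed others too, of which those of tumour hepatocytes and B cells are given. For the named genes, 1906 values under alternatives kept their direction and side of the threshold or were uncalled on both sides, 41 newly passed and 10 no longer passed, and 35 uncalled values had the opposite sign. Depth limits the NK-like cells of knockout 2 most, with 148766 UMIs, and where 1 library was left out of a group of 3 the spread is shared with the other group. In groups of 2 the 1 library left has no spread of its own, so calls kept there do not show stability.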

Other observations

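All tests in this part were chosen only after the results were seen. Tumour hepatocytes could be compared only between controls 1 and 3 (302 and 253 cells) and knockouts 1 and 3 (106 and 217 cells). In them, genes of the interferon gamma response and antigen presentation rose (median log2 fold change 0.56, 24 of 27 higher, 6 passing over the list alone, camera adjusted p = 1.37e-16, and adjusted p = 0.827 with an estimated correlation). Their first members by p were the GTPase genes Iigp1 (2.53, SE 0.40) and Igtp (2.28, SE 0.40) and the T cell attracting chemokine Cxcl9 (3.42, SE 0.62). Type I interferon response genes rose (0.64, 22 of 25 higher, adjusted p = 4.12e-08, and adjusted p = 0.827 with an estimated correlation), with the GTPase gene Ifi47 at 1.51 (SE 0.35). Immediate early genes fell (-0.61, 22 of 26 lower, adjusted p = 7.11e-07, and adjusted p = 0.827 with an estimated correlation), with Junb at -0.99 (SE 0.21) and Zfp36 at -1.05 (SE 0.25). Hepatocyte background genes rose in the same cells (0.44, 19 of 25 higher, adjusted p = 9.23e-07, and adjusted p = 0.827 with an estimated correlation). That call was lost without control 1 (adjusted p = 0.134) and without knockout 3 (adjusted p = 0.133). Oxidative phosphorylation genes rose too (0.15, 57 of 64 higher, adjusted p = 0.000412, and adjusted p = 0.882 with an estimated correlation). That call was lost without control 1 (adjusted p = 0.503) and without knockout 3 (median -0.07, adjusted p = 0.411). Erythroid genes, a background set, had -1.70 (adjusted p = 0.0861) and were called lower under the block (adjusted p = 9.66e-08, and adjusted p = 0.827 with an estimated correlation). Glycolysis genes had 0.07 (adjusted p = 0.119) and were called higher under it (adjusted p = 0.0224, and adjusted p = 0.887 with an estimated correlation). All 5 calls made without the block were kept under it. The interferon and immediate early calls were also kept without any 1 of the 4 libraries, with a largest adjusted p of 0.0101. Each of those fits leaves 1 library in a group, whose spread is assumed to be that of the other group, so this does not show that the calls are stable. The adjusted p of the single genes named was 0.999 in edgeR.

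In B cells, compared between 3 controls (293, 26 and 2404 cells) and knockouts 1 and 3 (576 and 873 cells), proliferation genes fell (-0.97, 27 of 27 lower, 7 passing over the list alone, camera adjusted p = 1.17e-21, and adjusted p = 0.827 with an estimated correlation), with the mitosis genes Birc5 at -2.16 (SE 0.59), Kif11 at -3.18 (SE 0.88) and Cdc20 at -2.36 (SE 0.67). Heat shock genes rose (0.65, 12 of 12 higher, adjusted p = 8.49e-13, and adjusted p = 0.827 with an estimated correlation), with Hspa1a at 1.51 (SE 0.48) and Dnajb1 at 1.36 (SE 0.52). Both calls were kept without any 1 library, but without either knockout library the group holds 1 library, whose spread is assumed to be that of the controls. Hepatocyte background genes fell in the same cells (-0.67, 23 of 24 lower, adjusted p = 0.00109, and adjusted p = 0.827 with an estimated correlation), and erythroid genes fell (-2.89, 4 of 4 lower, adjusted p = 0.0199, and adjusted p = 0.827 with an estimated correlation). Under the block 3 more lists passed in B cells, of NF-kB targets, ribosome biogenesis and oxidative phosphorylation (adjusted p = 0.000214 to 0.0479, and adjusted p = 0.827 to 0.98 with an estimated correlation).

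Xist, the RNA of the inactive X chromosome, was read in 77.26% of cells in control 1 and 79.04% in knockout 1, and in 0%, 0%, 0.01% and 0.16% in control 2, knockout 2, control 3 and knockout 3. Genes of the Y chromosome were read in 1.82% and 0.96% of cells in control 1 and knockout 1 and in 45.52% to 54.64% in the others. The study's description names male mice, and the transcripts of both libraries numbered 1 are those of females.

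Cd3d, Cd3e, Cd3g and Trac were higher in the NK-like cells of knockouts 1 and 3. Average T cells, or their RNA, would have to make up a further 21.23% (17.39% to 26.71% over the 4 genes) and 12.06% (8.85% to 28.99%) of the NK-like RNA in pairs 1 and 3 to give this, while 26 other abundant T cell genes allow 7.07% (95% interval 5.47% to 12.33%) and -2.40% (-3.79% to -0.23%), a ratio of 0.14 between the mean shares, and so speak against average T cells. A larger share of ILC1 cells explains a median of 6.7% of the rise (1.5% to 9%). Within the ILC1 subset Cd3d was higher in both pairs (268 and 783 CPM, 134 and 600 CPM, here of plain totals). Outside the subset Cd3d was higher in pair 1 (12.6 and 37.4 CPM) but not in pair 3 (32.3 and 29.8 CPM). T cells or innate-like cells unlike the average T cell were not excluded and could carry these genes, since the T cell genes Cd8a (16.63% and 12.16%) and Trbc2 (7.81% and 27.45%) need shares near those of the 4 genes in 1 or both pairs, while Trbc1 (11.05% and -4.99%), Cd8b1 (5.48% and -1.59%) and Lef1 (11.63% and 0.09%) need less in both.

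Ncr1, which carries Cre in the mice labelled knockout, was lower in NK-like cells (-1.17, SE 0.36, passing only under the block and with no filter on low counts). Other cells mixed in would lower the other 11 NK markers too, whose median was -0.19 (-0.53 to 0.49). A larger ILC1 share does not give it either, since in a cluster built without Ncr1 it was -1.27, and -1.20 with the ILC1 subset removed. Whether the Cre allele lowers Ncr1 or loss of Nr4a1 does stays open, since 0 libraries carry Cre with intact Nr4a1.

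Gzma, Gzmk, Ccl3, Ccl4, Cx3cr1, Klrg1 and Zeb2 were lower in T cells under the block, at a median of -1.29, and none of them passed with mice as units. Less NK cell RNA among the T cells would lower 27 abundant NK genes alike, and their median was 0.04 (95% interval -0.30 to 0.25). Gzma and Ncr1, abundant in NK-like cells too, were left out of the 27, and Ncr1 gave -1.62 in T cells under the block. Fewer cells of the cytotoxic CD8 cluster cannot give all of the fall of the 7 genes. Without that cluster their median was -1.11 and 5 of the 7 still passed under the block. Lower expression within T cells, or other effector cells lost from other clusters, could each give the rest.

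The T cell genes took the place of the lower NK-like share here after its values were seen. Tests of that share are given with the results. Of the clusters built without the 10 genes, a proliferating mixed cluster of T and NK cells (441 cells) joined the NK class, so the tests above used the largest NK cluster alone (1268 cells).

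The 6 libraries can be split 3 against 3 in 10 ways, too few to judge any count. The real split gave 1 gene in NK-like cells and the highest other 3, with 2 splits at least as high as the real one. For lists in NK-like cells it gave 8 and the highest other 15 (6 splits), for genes in other classes 0 and 1765 (10 splits), for lists in other classes 35 and 38 (7 splits), and for class shares 0 and 1 (10 splits). The 4 splits that held both libraries numbered 1 together, those with Xist, gave 1765, 263, 255 and 2 genes in other classes. A split that parted them gave 89, and the other 5 gave 0 to 3.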
